A study of Homo sapiens with 18 samples.

How the data were processed

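RNA sequencing was done on 18 libraries of NCI-H460 cells, 3 biological replicates for each of 3 populations (parental, resistant 1 and resistant 2) and 2 treatments. Cells were grown in RPMI-1640 with 10% fetal bovine serum, treated 24 h after seeding with DMSO (0.7% v/v) or with 2 µM ATRA and decitabine, 50 µM per the labels, and harvested at 72 h. RNA was isolated with RNeasy columns and DNase, and stranded mRNA libraries were made with the TruSeq kit. Per the submitters' processing notes, reads were checked with FastQC and MultiQC, aligned to GRCh38 (hg38) with STAR, counted with featureCounts and normalized with DESeq2. Their versions and the strand setting of the counting are not given in the sources used here. It is therefore unknown whether reads of overlapping genes on opposite strands were kept apart.

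The authors deposited a table per treatment, each normalized on its own. The deposited DMSO table holds a normalized signal per gene, from which whole reads were recovered by finding the step that makes the values of a library whole numbers within 0.01. The deposited ATRA and decitabine table holds another unit: its values lost their decimal points, and each was restored by finding, per gene, the powers of 10 that make its 9 values whole reads at a likely level. A gene was used where the posterior probability of its restored values reached 99%. Of 25121 genes with at least 10 normalized counts in at least 3 of 9 libraries, 19759 (78.7%) were resolved and 5362 were left out. Of these genes, 39.2% were resolved at mean levels under 30, 66.8% from 30 to 100, 87.7% from 100 to 1000 and 98.4% from 1000. The procedure was tested on the DMSO table with its decimal points removed, where 10 of 17348 resolved genes at the filter had a wrong value (16 of 156132 values). The spreads it assumes were set on the DMSO values, so this is not an independent error rate for the treated values. The restoration averaged a model without and a model with the population differences seen under DMSO. Without them, 0 genes at the filter that were resolved both ways were restored otherwise. Lowly expressed genes are thus under-represented under ATRA and decitabine, and genes such as CDA, CYP26A1 and CYP26B1 have no value there. The recovered depth was 116.9 to 140.9 M reads per DMSO library and 116.3 to 180.5 M reads over the resolved genes of the treated libraries. The libraries of a group differed by more than counting noise (chi-square per degree of freedom 9.28 to 224.9), so none repeats another.

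Within each table, log2(normalized count + 1) was tested with limma 3.58.1 (trend) in R 4.3.3, over genes with at least 10 normalized counts in at least 3 of 9 libraries (21643 genes with DMSO and 19759 with ATRA and decitabine). The comparisons were each resistant population against parental, their mean against parental and resistant 1 against resistant 2. P-values were adjusted by Benjamini-Hochberg and called under 0.05. The treatment response within each population and the differences of responses were tested on the recovered reads of all 18 libraries, scaled together by TMM (edgeR 4.0.16), as log2(CPM + 1) over 19946 genes. A total of 31 gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated per list. The lists described in the text are those that bear on the drugs, on resistance, or on what the treated cells expressed. Genes were named and placed by GENCODE 29 (41445 gene identifiers with a symbol). In simulated data, the test of resistant 1 against parental with DMSO (21643 genes) found 16.4%, 55.2% and 83.3% of genes changed by 1.5-fold, 2-fold and 4-fold, with 6.36% false calls. The test of the response in parental cells (20040 genes) found 38.8%, 76.1% and 89.4%, with 4.23% false calls. DESeq2 (1.42.0) gave 20.9% false calls in the first and served only as an alternative.

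Before the data were examined, the groups, comparisons, tests, thresholds, gene lists and the rule for named genes were written down. Per table, among genes with a symbol that were called in both resistant populations in 1 direction, with all 6 resistant libraries on 1 side of the 3 parental ones and a mean of at least 50 normalized counts, the 8 genes with the largest smaller change in each direction were selected. Between the resistant populations 4 per direction were selected, for the response in parental cells 8, and for the difference of responses 4, and per list up to 4 called members with a mean of at least 10 by size of change. A fixed set of genes of drug action, retinoid signalling, proliferation and cell adhesion was added. Some genes selected in these ways are not reported here. Folds against groups without a read use a floor of 3 counts per library. The alternatives tried were the compared groups alone, leaving out each library, edgeR and DESeq2 on reads, DESeq2 size factors over 18 libraries, and no filter or a filter at 50. Others were pseudocounts of 0.5 and 5, quantile normalization, TMM rescaling, a replicate block, a correlation estimated per list and a threshold of 2-fold. Restoration at posteriors of at least 0.9 and at a stricter level, log2(scaled count + 1) and a replicate block for the paired groups alone were added after the results were seen. The deviations of libraries from their group means were correlated between same-numbered libraries. All were above 0.1 between treated and untreated libraries of resistant 1 (0.473 to 0.938) and of resistant 2 (0.789 to 0.91), and between the untreated libraries of both (0.175 to 0.743). These are called the paired groups. The pairing is uncertain for untreated replicate 2 of resistant 1, which correlated better with another treated number (0.646 against 0.473). It is also uncertain for untreated replicate 1 of resistant 1 with resistant 2 (0.514 against 0.175). Other groups compared had a same-numbered pair under 0.1, and no label used here says what a number shares. Overlaps of lists that share controls were set against 20 simulations of unchanged groups. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and version 1.17.8 of data.table.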

Results

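Gene expression was measured by RNA sequencing in NCI-H460, an established human line of large-cell lung cancer, in 3 populations: the parental cells and 2 populations with resistance to decitabine combined with all-trans retinoic acid (ATRA), here called resistant 1 and resistant 2. Decitabine is a cytidine analogue that is built into DNA and traps DNA methyltransferases there, and ATRA is the ligand of the retinoic acid receptors. Each population received either the solvent (DMSO, 0.7% v/v) or 2 µM ATRA with decitabine, labelled as 50 µM, for 48 h, with 3 biological replicates per group and 18 libraries in all. The recovered depth was 116.9 to 140.9 M reads per library with DMSO and 116.3 to 180.5 M reads with ATRA and decitabine, the latter over the genes whose values could be restored. Levels within a treatment are given as normalized counts and levels across treatments as CPM, the reads scaled to library size, each as the mean ± SD of n = 3 libraries. In a principal component analysis of 2000 genes, the components took 47.0%, 29.6% and 18.4% of the variance and separated resistant 2 from parental, resistant 1 from the others, and treated from untreated parental libraries, in that order. Fibronectin (FN1), an extracellular matrix protein, took 0.292 to 0.327% of the reads of untreated parental libraries, 0.982 to 1.18% in resistant 1 and 4.47 to 5.08% in resistant 2.

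The comparison within DMSO asks how the resistant populations differed from the parental line while the drugs were absent. Both resistant populations had high levels of genes that were nearly silent in parental cells. IL7R, the alpha chain of the interleukin 7 receptor (ENSG00000168685, chromosome 5, 35852695 to 35879603, GRCh38), had 1 read over the 3 parental libraries and stood at 7763 ± 853 normalized counts (SD, n = 3) in resistant 1 and 1660 ± 455 in resistant 2. The neuropeptide FF receptor NPFFR2 likewise had 1 read in parental cells, against 1877 ± 51.9 and 1280 ± 86.6. The laminin chain LAMA4 stood at 3.33 ± 1.41 in parental cells, 1894 ± 415 in resistant 1 and 37096 ± 1456 in resistant 2. The matrix protein tenascin C (TNC) had 3 reads in parental cells, against 735 ± 156 and 1153 ± 349.9. VGLL3, a cofactor of TEAD transcription factors, went from 4.07 ± 1.28 to 2415 ± 63.9 and 12808 ± 2192, and the potassium channel gene KCNH1 from 6.94 ± 2.29 to 8449 ± 416 and 3550 ± 153. The protease inhibitor elafin (PI3) went from 3.28 ± 1.98 to 2558 ± 1227 and 6487 ± 1984, and the cancer-testis gene CSAG1, uncertain for its near-identical copies, from 6.93 ± 2.62 to 4918 ± 124 and 3580 ± 294. These 8 genes were selected by a rule fixed beforehand. Their log2 fold changes ran from 8.62 to 12.59 in resistant 1 and from 8.85 to 13.12 in resistant 2 (limma, Benjamini-Hochberg, highest adjusted p = 1.53e-08 and 5.81e-09). For genes with only a few reads in a group, the fitted fold change depends on the pseudocount of 1.

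The 8 genes selected among those lower in both resistant populations were all nuclear pseudogene copies of mitochondrial genes, so their values are uncertain. Transcripts of the mitochondrial genome itself had 0 reads in all 18 libraries. MTATP6P1 had 81333 ± 1544 normalized counts in parental libraries, no read in resistant 1 (at least 29600-fold lower, against a floor of 3 counts per library) and 1 read over the resistant 2 libraries. MTCO1P12 stood at 56458 ± 409.9 in parental cells and had no read in either resistant population (at least 20600-fold and 17800-fold lower). Among genes with their own protein product, 3 with low levels in both populations were chosen after their values were seen. The voltage-gated proton channel HVCN1 went from 7135 ± 673 to 8.29 ± 3.09 in resistant 1 and 42.3 ± 9.35 in resistant 2. The ephrin receptor EPHA3 went from 2684 ± 370.1 to 3.62 ± 3.28 and 23.4 ± 11.8, and the adhesion receptor ADGRG3 from 1566 ± 211 to 5.11 ± 1.93 and 18.4 ± 14.8 (limma, highest adjusted p = 9.52e-07 and 2.57e-06).

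Genes of the cell cycle were lower in both resistant populations and p53 target genes higher. Each gene list was fixed before the data were examined, and its counts adjusted over the list alone equal those over all genes tested unless both are given. Of 33 tested genes of G2/M and mitosis, all were lower in resistant 1 and in resistant 2. MKI67, the Ki-67 proliferation marker, stood at 58875 ± 5190 in parental cells, 23592 ± 2362 in resistant 1 (log2 fold change -1.32 ± 0.139 (SE), adjusted p = 1.25e-05) and 9354 ± 1918 in resistant 2 (-2.67 ± 0.139, adjusted p = 3.62e-08). HMMR, which acts on the mitotic spindle, went from 14904 ± 1588 to 3773 ± 97.8 and 1936 ± 449, and the mitotic kinase AURKB from 11680 ± 1444 to 2864 ± 174 and 1895 ± 277. Of 31 G1/S and DNA replication genes, 30 were lower in resistant 1 and 29 in resistant 2 and 0 were higher in either. The replication initiation factor MCM10 was lower (6628 ± 433 in parental, 1458 ± 50.4 and 906 ± 522 in resistant cells), as was the transcription factor E2F2 (3671 ± 546, 972 ± 102 and 267 ± 198). The list test (camera, inter-gene correlation preset to 0.01) gave, for the G2/M list, adjusted p = 1.81e-13, or 0.259 with an estimated correlation, in resistant 1 and adjusted p = 1.06e-15, or 0.375 with an estimated correlation, in resistant 2. For the G1/S list it gave adjusted p = 7.94e-09, or 0.365 with an estimated correlation, in resistant 1 and adjusted p = 1.44e-10, or 0.406 with an estimated correlation, in resistant 2. With DMSO, the only list calls that hold with an estimated correlation are those of the EMT and TGF-beta lists in resistant 2.

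CDKN1A, which encodes the CDK inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), stood at 5050 ± 689.8 in parental cells, 68124 ± 4657 in resistant 1 (log2 fold change 3.76 ± 0.139 (SE), adjusted p = 3.15e-09) and 122123 ± 22858 in resistant 2 (4.59 ± 0.139, adjusted p = 6.23e-10). Of 31 tested p53 target genes, 23 were higher and 2 lower (23 and 3 adjusted over the list alone) in resistant 1 and 28 were higher and 1 lower in resistant 2. The stress-induced cytokine GDF15 went from 2659 ± 1037 to 38209 ± 10716 and 21862 ± 10532. TP53INP1, a p53-induced nuclear protein, went from 476 ± 79.1 to 3783 ± 365 and 9411 ± 853, and SPATA18, which takes part in mitochondrial quality control, from 241 ± 24.7 to 3343 ± 119.6 and 5128 ± 410.2. The camera test gave adjusted p = 5.77e-06, or 0.165 with an estimated correlation, in resistant 1 and adjusted p = 8.63e-10, or 0.0827 with an estimated correlation, in resistant 2.

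Among genes tied to the action of decitabine, the maintenance methyltransferase DNMT1 (ENSG00000130816, chromosome 19, 10133345 to 10231286), whose protein the drug traps, stood at 27364 ± 2500 in parental cells, 10226 ± 414 in resistant 1 (log2 fold change -1.42 ± 0.136 (SE), adjusted p = 6.17e-06) and 7192 ± 1568 in resistant 2 (-1.95 ± 0.136, adjusted p = 3.49e-07). The de novo methyltransferase DNMT3B was lower in both (1064 ± 138, 385 ± 46.2 and 374 ± 67.8), while DNMT3A was lower in resistant 1 (-0.43, adjusted p = 0.00624) and higher in resistant 2 (0.78, adjusted p = 8.94e-05). UHRF1, which brings DNMT1 to replicating DNA, went from 4605 ± 1471 to 1614 ± 396 and 967 ± 665, and the demethylase TET1 from 1686 ± 191 to 429 ± 78.5 and 274 ± 65.5. Of the 17 tested writers, readers and erasers of DNA methylation, 2 were higher and 10 lower in resistant 1 (adjusted p = 0.00393, or 0.165 with an estimated correlation). In resistant 2, 3 were higher and 7 lower, and the list did not pass (adjusted p = 0.28).

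SLC29A1, the equilibrative transporter that carries nucleosides into cells (ENSG00000112759, chromosome 6, 44219505 to 44234151), stood at 7557 ± 684 in parental cells, 3435 ± 259 in resistant 1 (-1.14, adjusted p = 0.0059) and 744 ± 396 in resistant 2 (-3.48, adjusted p = 1.31e-06). Its relative SLC29A2 went from 3194 ± 575 to 1633 ± 72.5 and 221 ± 33.1. Deoxycytidine kinase (DCK), which activates decitabine, did not pass in resistant 1 (3769 ± 434 and 3563 ± 313, adjusted p = 0.591) and was lower in resistant 2 (2159 ± 155, adjusted p = 9.97e-05). Cytidine deaminase (CDA), which inactivates it, was lower in resistant 2 (-1.53, adjusted p = 0.000563). Its higher level in resistant 1 (0.92, adjusted p = 0.015) no longer passed with quantile normalization or without parental replicate 2, parental replicate 3 or resistant 1 replicate 3 (0.0539 to 0.0575). SAMHD1, a hydrolase of deoxynucleotide triphosphates, was lower in both (-0.52, adjusted p = 0.0114, and -1.29, adjusted p = 1.83e-05). RRM2B, the p53-induced subunit of ribonucleotide reductase, went the other way, from 6813 ± 899 to 22165 ± 1345 and 60067 ± 9020. Of 18 tested genes of decitabine uptake and metabolism, 2 were higher and 11 lower in resistant 1 (adjusted p = 0.0295, or 0.365 with an estimated correlation). In resistant 2, 3 were higher and 14 lower (adjusted p = 0.00693, or 0.375 with an estimated correlation).

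The efflux pump ABCB1 (ENSG00000085563, chromosome 7, 87503633 to 87713323) parted the populations: it stood at 842 ± 51.6 in parental cells, 12704 ± 632 in resistant 1 (3.91 ± 0.152 (SE), adjusted p = 4.69e-09) and 564 ± 127 in resistant 2 (-0.60 ± 0.152, adjusted p = 0.00497). ABCG2, another drug efflux pump, was lower in resistant 2 (8907 ± 914 in parental, 1465 ± 209 in resistant 2). The list of 15 efflux transporters passed in neither population (adjusted p = 0.266 and 0.97), and in resistant 2 its median (0.03) and mean (-0.15) had opposite signs. Of the retinoid receptors, RARB was higher in resistant 2 (1396 ± 94.7 in parental, 1266 ± 98.1 in resistant 1, adjusted p = 0.436, and 3392 ± 669.5 in resistant 2, adjusted p = 1.92e-05). RARG (adjusted p = 0.139 and 0.062) and RXRA (0.143 and 0.404) passed in neither, although RARG passed in resistant 2 without resistant 2 replicate 2 (0.0388) and RXRA in resistant 1 without parental replicate 3 (0.0218). RARA did not pass in resistant 2 (adjusted p = 0.96), and its lower level in resistant 1 (-0.42, adjusted p = 0.0445) no longer passed with TMM rescaling or without any 1 of 5 libraries (0.0515 to 0.177). CRABP2, which carries retinoic acid to the receptors, was lower in both (210.1 ± 16.001, 82.6 ± 12.99 and 91.5 ± 11.6). The retinoic acid hydroxylase CYP26B1 was lower in resistant 1 (-2.13, adjusted p = 1.19e-05) and did not pass in resistant 2 (adjusted p = 0.17). Its relative CYP26A1 was higher in both (3.66 ± 0.985, 15.98 ± 5.498 and 50.8 ± 11.1, adjusted p = 0.000572 and 3.38e-06). The retinaldehyde reductase DHRS3 was higher in resistant 2 (1.98, adjusted p = 5.02e-06) and did not pass in resistant 1 (0.03, adjusted p = 0.901). Of 15 genes of retinoid metabolism, 8 were higher and 2 lower in resistant 2 (adjusted p = 0.0485, or 0.291 with an estimated correlation), led by the retinaldehyde dehydrogenase ALDH1A1 (9158 ± 751 to 179996 ± 39414).

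Genes of mesenchymal cells and of invasion were mostly higher, with different leading genes in the 2 populations. N-cadherin (CDH2) stood at 341 ± 31.7 in parental cells, 2200 ± 284 in resistant 1 (2.68, adjusted p = 1.79e-08) and 9105 ± 682 in resistant 2 (4.74, adjusted p = 2.24e-10). Vimentin (VIM) was higher in resistant 1 (0.73, adjusted p = 3.36e-05). The call in resistant 2 (0.23, adjusted p = 0.0393) ended with quantile normalization or without any 1 of 5 libraries (0.0522 to 0.127), and E-cadherin (CDH1) was below the level at which genes were tested. Of 29 genes of epithelial-mesenchymal transition (EMT), 19 were higher and 7 lower in resistant 1 (adjusted p = 0.00273, or 0.165 with an estimated correlation). In resistant 2, 22 were higher and 5 lower (adjusted p = 2.42e-05, or 0.0469 with an estimated correlation). The matrix protein SPARC stood at 2.07 ± 1.796 in parental cells, 8291 ± 223 in resistant 1 and 27.6 ± 7.15 in resistant 2, and the gelatinase MMP2 at 3.64 ± 1.39, 998 ± 40.8 and 110687 ± 33354. Of 26 TGF-beta response genes, 18 were higher and 0 lower in resistant 2 (adjusted p = 6.38e-07, or 0.0469 with an estimated correlation). The metalloproteinase inhibitor TIMP3 stood at 15.3 ± 13.3 in parental cells and 32762 ± 9190 there, and thrombospondin 1 (THBS1) at 523 ± 169.8 and 20357 ± 5054. In resistant 1, 11 were higher and 8 lower and the list did not pass (adjusted p = 0.148).

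Of 38 genes of cell migration and invasion, 20 were higher and 5 lower in resistant 1 (adjusted p = 0.0024, or 0.259 with an estimated correlation). In resistant 2, 21 were higher and 5 lower (22 and 5 adjusted over the list alone) (adjusted p = 0.0101, or 0.375 with an estimated correlation). The collagenase MMP1 stood at 1578 ± 320.0 in parental cells, 338468 ± 23622 in resistant 1 and 8284 ± 1712 in resistant 2. The integrin ITGA3 stood at 2964 ± 291, 93003 ± 13730 and 84054 ± 12861, and the chemokine receptor CXCR4 at 1.66 ± 0.497, 41.1 ± 6.9996 and 695 ± 439.5. Of 26 genes of inflammatory and senescence-associated secretion, 17 were higher and 3 lower in resistant 1 (adjusted p = 0.00227, or 0.388 with an estimated correlation). In resistant 2, 20 were higher and 0 lower (20 and 1 adjusted over the list alone) (adjusted p = 1.58e-05, or 0.406 with an estimated correlation). Insulin-like growth factor binding protein 5 (IGFBP5) stood at 271 ± 91.1, 262 ± 23.4 and 334294 ± 13143 in parental, resistant 1 and resistant 2 cells. IGFBP7 stood at 344 ± 42.7, 8579 ± 232 and 23658 ± 2172, and complement C3 at 71.6 ± 6.02, 967 ± 419.7 and 19952 ± 3438. The list of 25 epithelial identity and junction genes passed in neither (adjusted p = 0.212 and 0.466), with the claudin CLDN7 lower in both (628 ± 86.04, 90.3 ± 5.29 and 19.01 ± 7.38). Of 9 fibroblast markers, 1 was higher and 6 lower (2 and 6 adjusted over the list alone) in resistant 1 (adjusted p = 0.016, or 0.165 with an estimated correlation). The collagen COL3A1 stood at 6475 ± 1063 in parental cells and 28.2 ± 4.48 in resistant 1. In resistant 2 the fibroblast list did not pass (adjusted p = 0.97), and the immune (0.123 and 0.97) and endothelial lists (0.0852 and 0.302) passed in neither population.

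Cancer-testis genes, which are normally restricted to germ cells, were mostly higher in resistant 1. Of 22 tested, 13 were higher and 3 lower (14 and 3 adjusted over the list alone) in resistant 1 (adjusted p = 0.000331, or 0.165 with an estimated correlation). In resistant 2, 7 were higher and 4 lower and the list did not pass (adjusted p = 0.599). MAGEA4 had 4 reads over the parental libraries and stood at 53965 ± 1703 in resistant 1 and 17.7 ± 13.9 in resistant 2, and MAGEA12 went from 7.13 ± 2.26 to 4628 ± 388 and 3030 ± 355. These families have near-identical copies between which reads can be split, so single values are uncertain. Cholesterol synthesis genes were lower: of 22 tested, 2 were higher and 16 lower (2 and 18 adjusted over the list alone) in resistant 1 (adjusted p = 0.000112, or 0.165 with an estimated correlation). In resistant 2, 1 was higher and 20 lower (adjusted p = 1.54e-07, or 0.0827 with an estimated correlation). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, stood at 10045 ± 458, 2923 ± 167 and 566 ± 76.4 in parental, resistant 1 and resistant 2 cells. Of 28 NRF2 target genes, which answer oxidative stress, 3 were higher and 17 lower in resistant 1 (adjusted p = 0.00111, or 0.259 with an estimated correlation). In resistant 2, 7 were higher and 11 lower and the list did not pass (adjusted p = 0.526). The aldo-keto reductase AKR1C2, which has close paralogs, stood at 68575 ± 8099, 5245 ± 351 and 103520 ± 10577.

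**Figure D1:**
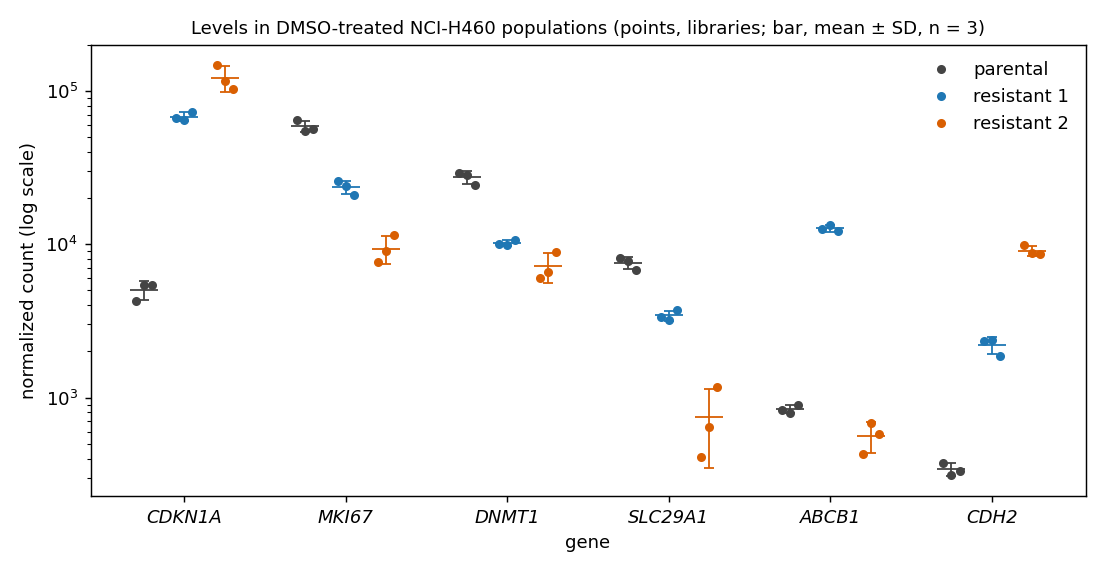
Normalized counts with DMSO (log axis) of 6 genes in the parental, resistant 1 and resistant 2 populations. Points are libraries, and bars give the mean ± SD (n = 3). CDKN1A was at 5050, 68124 and 122123 on average, MKI67 at 58875, 23592 and 9354, and ABCB1 at 842, 12704 and 564.

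Over all 21643 genes tested with DMSO, 12102 passed in resistant 1 (limma, adjusted p under 0.05), 6348 higher and 5754 lower, and 13402 passed in resistant 2, 6951 higher and 6451 lower. For the mean of both resistant populations against parental, 13300 genes passed. A total of 7782 genes passed in both in the same direction, 4107 higher and 3675 lower, of which 3505 reached 2-fold in both, and 1234 passed in opposite directions. Quantile normalization shifted the median log2 fold change of all genes by -0.121 in resistant 1 and -0.108 in resistant 2 and turned the majority, with 5673 higher and 6882 lower in resistant 1 and 6139 and 7324 in resistant 2. The log2 fold changes of the 2 populations correlated across genes, which are not independent replicates, with r = 0.544, where unchanged groups simulated against the same parental libraries gave 0.503. The covariance was 1.47 against 0.0372 in the simulation, a difference of 1.43, and 71.9% of genes had the same sign against 66.7%. Independent lists of this size would share 2039 higher and 1715 lower genes. Part of the excess can come from the shared parental libraries, since 3 libraries cannot be split into parts of at least 2 libraries each. The p-values measure the spread between these replicate libraries, and with 1 population per origin they do not measure how far another selection would differ.

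The resistant populations were also compared with each other, to ask whether they had become alike. Single genes were read in 1 population and hardly or not at all in the other, and the cell cycle and p53 changes differed in size. SLFN11, a protein that blocks replication under DNA damage, stood at 5218 ± 591 in parental cells and 4328 ± 139 in resistant 1 (adjusted p = 0.138 between them) and had no read in resistant 2 (at least 1360-fold higher in resistant 1). The cancer-testis gene PASD1 had no read in parental or resistant 2 libraries and stood at 8358 ± 108 in resistant 1, at least 2760-fold and 2630-fold higher. PAGE5 had 1 read in parental libraries, 1 read in resistant 2 and 7787 ± 111 normalized counts in resistant 1. Higher in resistant 2, CYP24A1, the vitamin D hydroxylase, stood at 239.6 ± 91.1 in parental cells and 62463 ± 17162 in resistant 2, with 2 reads over the resistant 1 libraries. Ceruloplasmin (CP) stood at 35.6 ± 11.2, 5.79 ± 0.58 and 16034 ± 948 in parental, resistant 1 and resistant 2 cells. CSF2RB, the shared beta chain of cytokine receptors, had 0 and 3 reads in parental and resistant 1 cells and stood at 3296 ± 1770 in resistant 2. The pseudogene ALG1L13P is uncertain (525 ± 28.9 in parental, 1 read in resistant 1, 4548 ± 1026 in resistant 2). Of 33 G2/M genes, 25 were higher and 2 lower in resistant 1 than in resistant 2 (adjusted p = 1.17e-05, or 0.681 with an estimated correlation). Of 26 TGF-beta response genes, 1 was higher and 17 lower in resistant 1 (adjusted p = 9.29e-06, or 0.0985 with an estimated correlation), where TIMP3 stood at 1866 ± 995. Of 9 fibroblast markers, 2 were higher and 6 lower in resistant 1 (adjusted p = 0.0101, or 0.154 with an estimated correlation), and of 29 mesenchymal and EMT genes, 6 were higher and 14 lower (adjusted p = 0.0135, or 0.154 with an estimated correlation). Of 31 p53 targets, 1 was higher and 21 lower (1 and 25 adjusted over the list alone) in resistant 1 (adjusted p = 4.93e-05, or 0.169 with an estimated correlation). In all, 11555 genes passed, 5928 higher in resistant 1 and 5627 higher in resistant 2.

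The same populations were compared under ATRA and decitabine, to ask which differences stand while the drugs are present. More of the listed epithelial genes were then lower than higher in both resistant populations, and most G2/M genes stayed lower. These values were restored from a table whose decimal points were lost, and 5362 of 25121 genes at the filter were left out. The netrin receptor UNC5C had 4 reads over the parental libraries and stood at 221 ± 48.8 in resistant 1 and 3277 ± 664 in resistant 2. LYPD6B, a membrane-anchored modulator of nicotinic receptors, stood at 62.2 ± 5.398, 9026 ± 873 and 3319 ± 366. The chromodomain protein gene CDYL2 stood at 183 ± 37.2, 8969 ± 810.3 and 23689 ± 4620, and NPFFR2 at 33.7 ± 4.51, 2180 ± 54.6 and 1649 ± 197. The other genes selected as higher were FRMPD4, DIRAS2, SHROOM2 and the long noncoding RNA LINC00900 (1 read in parental, 69.4 ± 7.23 and 309 ± 59.1 in resistant cells). On the lower side were again copies of mitochondrial genes, led by MTATP6P1 (74056 ± 751 in parental cells and no read in either resistant population). TRIM49C, a TRIM family gene with near-identical copies and so uncertain, stood at 7087 ± 1178 in parental cells, 4.76 ± 4.49 in resistant 1 and 1.54 ± 2.66 in resistant 2. The pseudogene TRIM53BP stood at 2939 ± 567, 1.28 ± 2.21 and 0.

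Under ATRA and decitabine, CDH1 stood at 1403 ± 14.8 in parental, 61.2 ± 7.96 in resistant 1 (-4.50, adjusted p = 1.11e-08) and 42.2 ± 13.4 in resistant 2 (-5.07, adjusted p = 2.32e-09). OVOL1, a transcription factor of epithelial cells, stood at 449.7 ± 48.5, 15.2 ± 2.18 and 4.66 ± 1.74. Of 25 epithelial genes, 5 were higher and 14 lower (5 and 15 adjusted over the list alone) in resistant 1 (adjusted p = 0.00945, or 0.272 with an estimated correlation). In resistant 2, 5 were higher and 18 lower (adjusted p = 0.00123, or 0.313 with an estimated correlation). Of 6 squamous and basal markers, 0 were higher and 5 lower in resistant 1 (adjusted p = 0.00672, or 0.272 with an estimated correlation). Keratin 6A (KRT6A) stood at 662 ± 57.3 in parental cells, 3 reads over the resistant 1 libraries and no read in resistant 2 (at least 184-fold lower). In resistant 2, 0 were higher and 6 lower (adjusted p = 0.00123, or 0.313 with an estimated correlation). The change was not confined to epithelial lists. Of 9 fibroblast markers, 1 was higher and 7 lower in resistant 1 (adjusted p = 0.00945, or 0.272 with an estimated correlation), and of 6 immune cell markers, 0 were higher and 5 lower (adjusted p = 0.02, or 0.272 with an estimated correlation). In resistant 2 neither passed (adjusted p = 0.0721 and 0.0586). Vimentin was higher in both (1.35 and 1.22, adjusted p = 5.67e-07 and 8.78e-07). Of 33 G2/M genes, 0 were higher and 28 lower (0 and 29 adjusted over the list alone) in resistant 1 (adjusted p = 1.45e-06, or 0.517 with an estimated correlation). In resistant 2, 1 was higher and 29 lower (adjusted p = 9.64e-07, or 0.402 with an estimated correlation). MKI67 stood at 67027 ± 4019, 37479 ± 5249 and 22868 ± 3707, and DNMT1 at 26055 ± 951, 14348 ± 766 and 13317 ± 1909, lower in both (highest adjusted p of the pair in either population = 7.82e-05 and 2.36e-06).

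CDKN1A no longer stood far apart under treatment: it was at 64364 ± 2858 in parental cells, 74348 ± 2916 in resistant 1 (0.21, adjusted p = 0.0228) and 116444 ± 8589 in resistant 2 (0.85, adjusted p = 6.83e-07). The difference in resistant 1 turned to -0.18 with quantile normalization, and it no longer passed with TMM rescaling, edgeR or DESeq2, or without parental replicate 2, parental replicate 3, resistant 1 replicate 2 or resistant 1 replicate 3 (0.0515 to 0.0989). Of 31 p53 targets, 5 were higher and 19 lower in resistant 1 (adjusted p = 0.00616, or 0.517 with an estimated correlation). In resistant 2, 14 were higher and 10 lower (15 and 10 adjusted over the list alone), the median and mean (0.20 and -0.01) had opposite signs, and the list did not pass (adjusted p = 0.895). SLC29A1 was lower in both (-0.58, adjusted p = 0.0109, and -2.07, adjusted p = 6.34e-07). ABCB1 was higher in resistant 1 (1154 ± 37.5 to 14713 ± 350.1) and lower in resistant 2 (-0.45, adjusted p = 0.0388, not passing without any 1 of 6 libraries (0.0512 to 0.0918)). DCK passed in neither (adjusted p = 0.339 and 0.231). CRABP2 stood at 2273 ± 122, 272.9 ± 37.5 and 178 ± 31.1 in parental, resistant 1 and resistant 2 cells. Of 22 retinoic acid response genes, 2 were higher and 17 lower in resistant 1 (adjusted p = 0.00182, or 0.136 with an estimated correlation). In resistant 2, 5 were higher and 13 lower and the list did not pass (adjusted p = 0.121). Of 18 cancer-testis genes, 1 was higher and 13 lower (1 and 14 adjusted over the list alone) in resistant 2 (adjusted p = 0.000638, or 0.313 with an estimated correlation), with MAGEC2 at 2782 ± 123, 153 ± 34.5 and 15.4 ± 14.6. In resistant 1, 5 were higher and 10 lower and the list did not pass (adjusted p = 0.436).

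Between the treated resistant populations, SLFN11 (4965 ± 145 in resistant 1, 8 reads over the resistant 2 libraries), ZNF677, a zinc finger gene (1534 ± 276 and 2 reads), and the pseudogene ZNF818P (1696 ± 155 and 0.384 ± 0.665) were selected as higher in resistant 1. SLITRK6, a neuronal membrane protein (13.999 ± 4.403 and 6934 ± 689), THSD7A (3.998 ± 1.18 and 2181 ± 378), the Wnt signalling gene DAAM2 (14.1 ± 1.62 and 5431 ± 604) and VWA2 (4.003 ± 1.63 and 1725 ± 376) were selected as higher in resistant 2. Of 19759 genes tested, 13191 passed in resistant 1 (limma, 6972 higher and 6219 lower), 14216 in resistant 2 (7599 and 6617), 14109 for the mean of both populations and 11475 between the populations (5704 higher and 5771 lower in resistant 1). In both resistant populations 4872 were higher and 4302 lower, where independent lists would share 2681 and 2083. The fold changes correlated across genes with r = 0.655 (0.477 simulated), with a covariance of 1.46 against 0.0183 simulated, a difference of 1.44, and part of this excess too can come from the shared parental libraries. Among 18449 genes tested under both treatments, 7080 passed in the same direction in resistant 1 and 998 in opposite directions, and 8204 and 1110 did so in resistant 2, in tests made within each treatment's own normalization.

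The treatment response compares ATRA and decitabine with DMSO within each population, over reads recovered from both tables and scaled together. In parental cells the response was wide: germline genes, p53 targets, retinoic acid response genes and epithelial genes rose. CCNA1, the cyclin A of the germline (ENSG00000133101, chromosome 13, 36431520 to 36442882), rose from 0.941 ± 0.313 to 429.7 ± 87.9 CPM (SD, n = 3; log2 response 7.79 ± 0.195 (SE), adjusted p = 6.05e-15). GPX2, a glutathione peroxidase, rose from 0.0476 ± 0.0344 to 129 ± 14.9 CPM, and the imprinted noncoding RNA MEG3 from 0.00278 ± 0.00481 to 106 ± 13.6 CPM. TEX13C, a testis-expressed gene, rose from 0.0114 ± 0.00459 to 83.2 ± 1.99 CPM, and the phosphodiesterase PDE4C from 0.18 ± 0.0214 to 79.03 ± 14.7 CPM. TRIM43B (198 ± 43.1 CPM), TAF11L14 (63.1 ± 12.4) and TRIM49C (51.9 ± 8.74, at least 2010-fold higher than 0 reads) also rose, and as members of families of near-identical copies their values are uncertain. SCD, the stearoyl-CoA desaturase, fell from 2745 ± 42.04 to 494 ± 37.3 CPM, and HVCN1 from 60.9 ± 5.08 to 9.33 ± 0.378 CPM. HOPX, a homeodomain protein of alveolar cells, fell from 97.2 ± 4.12 to 13.5 ± 1.62 CPM, and RPL22L1, a ribosomal protein paralog, from 195 ± 22.1 to 33.2 ± 3.24 CPM. The chemokine CXCL2, the prostaglandin D synthase HPGDS and MCTP1 were also selected as fallen (log2 responses -2.95, -2.74 and -2.62). Responses are on the log2(CPM + 1) scale, which understates the change of low genes.

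Of 31 p53 targets, 27 rose and 0 fell (28 and 0 adjusted over the list alone) in parental cells (adjusted p = 8.1e-11, or 0.0362 with an estimated correlation). CDKN1A rose from 43.2 ± 6.25 to 471 ± 18.4 CPM (log2 response 3.43 ± 0.116 (SE), adjusted p = 2.3e-13), TP53INP1 from 4.06 ± 0.606 to 83.8 ± 3.48 CPM and SPATA18 from 2.06 ± 0.198 to 48.8 ± 4.46 CPM. Of 22 retinoic acid response genes, 20 rose and 1 fell (adjusted p = 2.75e-07, or 0.00288 with an estimated correlation). The transglutaminase TGM2 rose from 6.24 ± 1.68 to 198 ± 6.21 CPM, DHRS3 from 10.2 ± 1.75 to 91.02 ± 7.44 CPM and CRABP2 from 1.796 ± 0.168 to 16.6 ± 0.829 CPM. RARB (1.29), RARA (0.69) and RARG (0.72) rose as well (limma, highest adjusted p = 0.000994), and RXRA did not pass (0.41, adjusted p = 0.0964) except without parental DMSO replicate 2 (0.0426). Of 18 cancer-testis genes, 15 rose and 1 fell (adjusted p = 2.75e-07, or 0.0362 with an estimated correlation). MAGEA4 rose (43.9 ± 3.497 CPM from 4 reads over the untreated libraries), as did MAGEC2 and TDRD1, which had no read in untreated cells (at least 789-fold and 511-fold higher). Of 25 epithelial genes, 18 rose and 2 fell (adjusted p = 2.15e-05, or 0.0362 with an estimated correlation). Desmoplakin (DSP) rose from 2.78 ± 0.431 to 95.96 ± 13.8 CPM, the splicing factor ESRP1 from 0.891 ± 0.354 to 21.4 ± 3.35 CPM and CDH1 from 0.0116 ± 0.0101 to 10.3 ± 0.163 CPM. Of 6 squamous markers, 6 rose and 0 fell (adjusted p = 0.000671, or 0.0362 with an estimated correlation). Of 6 immune cell markers, 6 rose and 0 fell (adjusted p = 0.00167, or 0.0362 with an estimated correlation), and the lysosomal protein gene LAPTM5 rose from 0.0142 ± 0.00939 to 8.64 ± 0.287 CPM. VIM fell from 1263 ± 44.8 to 366 ± 7.87 CPM and CDH2 rose from 2.91 ± 0.237 to 10.9 ± 0.413 CPM.

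Genes of other lists fell in treated parental cells. Of 21 cholesterol synthesis genes, 1 rose and 17 fell (adjusted p = 2.65e-05, or 0.0891 with an estimated correlation). The sterol carrier STARD4 fell from 493 ± 129 to 98.5 ± 16.6 CPM and lanosterol synthase (LSS) from 33.2 ± 8.29 to 9.65 ± 0.117 CPM. Of 28 NRF2 targets, 3 rose and 22 fell (3 and 24 adjusted over the list alone) (adjusted p = 3.55e-07, or 0.0935 with an estimated correlation), with the aldo-keto reductase AKR1C3 at 505 ± 37.5 CPM before and 109 ± 8.76 after. Of 27 genes of the unfolded protein and integrated stress response, 7 rose and 15 fell (adjusted p = 0.00444, or 0.49 with an estimated correlation). PHGDH, an enzyme of serine synthesis, fell from 387 ± 26.6 to 80.3 ± 4.32 CPM and the amino acid stress gene TRIB3 from 354 ± 34.7 to 64.3 ± 9.42 CPM. Of 33 G2/M genes, 1 rose and 15 fell (adjusted p = 0.00444, or 0.744 with an estimated correlation), and MKI67 did not pass (502 ± 39.6 and 491 ± 32.1 CPM, adjusted p = 0.862). DNMT3B rose from 9.09 ± 1.19 to 21.3 ± 1.87 CPM, while DNMT3A (adjusted p = 0.512) and ABCB1 (0.252) did not pass. DNMT1 (-0.29, adjusted p = 0.058), SLC29A1 (-0.55, 0.0573) and DCK (-0.25, 0.0821) lay close to the threshold. DNMT1 passed as lower without any 1 of 9 libraries (0.00372 to 0.0385), SLC29A1 without any 1 of 9 libraries (0.00411 to 0.0429) and DCK without any 1 of 8 libraries (0.00842 to 0.042). Over 19946 genes, 12735 passed in parental cells, 6886 rising and 5849 falling, of which 1798 rose and 702 fell by at least 2-fold.

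Retinoic acid response and epithelial genes rose in the resistant populations as well. Fewer genes passed: 5729 in resistant 1 (2972 rose and 2757 fell, 354 and 73 of them by at least 2-fold) and 3889 in resistant 2 (2055 and 1834, with 216 and 88 by at least 2-fold). With same-numbered treated and untreated libraries as a replicate block, more passed: 8030 in resistant 1 (3874 rose and 4156 fell) and 5993 in resistant 2 (2908 and 3085). Of 22 retinoic acid response genes, 17 rose and 0 fell in resistant 1 (adjusted p = 1.05e-09, or 0.000554 with an estimated correlation and 0.0485 with a replicate block as well). In resistant 2, 12 rose and 2 fell (adjusted p = 1.44e-07, or 0.0024 with an estimated correlation and 0.113 with a replicate block as well). DHRS3 rose from 10.5 ± 1.36 to 139 ± 5.87 CPM in resistant 1 and from 39.97 ± 11.3 to 225 ± 17.7 CPM in resistant 2. TGM2 rose from 5.098 ± 1.57 to 91.3 ± 18.4 CPM and from 167 ± 36.9 to 1124 ± 116 CPM. RARA rose in both (1.19 and 1.26, adjusted p = 2.89e-05 and 2.84e-05), as did RARB (1.55 and 0.81). Of 25 epithelial genes, 14 rose and 3 fell (15 and 3 adjusted over the list alone) in resistant 1 (adjusted p = 1.16e-06, or 0.027 with an estimated correlation and 0.108 with a replicate block as well). In resistant 2, 12 rose and 3 fell (adjusted p = 7.41e-06, or 0.0344 with an estimated correlation and 0.113 with a replicate block as well). In resistant 1, of 9 fibroblast markers 5 rose and 1 fell (adjusted p = 0.021, or 0.0894 with an estimated correlation), and of 6 immune cell markers 2 rose and 0 fell (adjusted p = 0.0413, or 0.212 with an estimated correlation), without passing with a replicate block (0.0611). In resistant 2 neither passed (adjusted p = 0.284 and 0.225). Of 18 cancer-testis genes, 6 rose and 0 fell (6 and 1 adjusted over the list alone) in resistant 2 (adjusted p = 0.000756, or 0.226 with an estimated correlation). In resistant 1, 6 rose and 3 fell, and the list did not pass (adjusted p = 0.131). CLDN7 rose from 0.779 ± 0.041 to 16.9 ± 2.003 CPM and from 0.16 ± 0.062 to 7.21 ± 0.677 CPM. CDKN1A did not pass in resistant 1 (588 ± 42.6 and 506 ± 23.01 CPM, adjusted p = 0.191). It fell in resistant 2 (from 1027 ± 189 to 762 ± 51.1 CPM, adjusted p = 0.0178), a call that ended without resistant 2 treated replicate 3 or resistant 2 DMSO replicate 1 (0.0748 to 0.134). Of 31 p53 targets, 15 rose and 1 fell (16 and 1 adjusted over the list alone) in resistant 1 (adjusted p = 0.000968, or 0.311 with an estimated correlation). In resistant 2, 5 rose and 2 fell (6 and 2 adjusted over the list alone), or 11 and 2 with a replicate block, and the list did not pass (adjusted p = 0.0743).

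In resistant 2, genes of the cell cycle rose with treatment. Of 33 G2/M genes 30 rose and 0 fell (adjusted p = 1.67e-16, or 0.226 with an estimated correlation). Of 31 G1/S genes 25 rose and 0 fell (26 and 1 adjusted over the list alone) (adjusted p = 1.46e-11, or 0.389 with an estimated correlation). MKI67 rose from 78.7 ± 16.4 to 149.9 ± 25.8 CPM (log2 response 0.93 ± 0.144 (SE), adjusted p = 0.000246), and DNMT1 from 60.5 ± 13.4 to 87.3 ± 13.5 CPM (adjusted p = 0.00654). In resistant 1 neither passed (0.32 and 0.14, adjusted p = 0.114 and 0.449), and the lists did not pass either (adjusted p = 0.246 and 0.134). With a replicate block MKI67 passed as higher there (adjusted p = 0.00396), as did the G1/S list, of which 13 rose and 1 fell (adjusted p = 0.0107, or 0.7045 with an estimated correlation). Of 22 targets of the coactivators YAP and TAZ, 2 rose and 10 fell (3 and 11 adjusted over the list alone) in resistant 1 (adjusted p = 0.0331, or 0.46 with an estimated correlation). In resistant 2, 2 rose and 12 fell (2 and 13 adjusted over the list alone) (adjusted p = 0.000369, or 0.226 with an estimated correlation). ANKRD1, a target of both, fell from 239.5 ± 48.1 to 115 ± 19.6 CPM and from 415 ± 136 to 143 ± 6.45 CPM. VIM fell in both (-1.28 and -0.94), and the drug efflux pump ABCG2 rose from 87.8 ± 2.59 to 256 ± 17.9 CPM and from 12.3 ± 1.81 to 32.5 ± 9.51 CPM. ABCB1 passed in neither (adjusted p = 0.596 and 0.405) except as higher in resistant 2 without resistant 2 treated replicate 1 (0.0127) or with a replicate block (0.0235).

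The difference of responses was tested directly, to ask which parts of the parental response the resistant populations lacked. For 8448 genes the response of resistant 1 differed from that of parental cells (3468 above and 4980 below it), and for 9551 genes that of resistant 2 did (4016 and 5535), with 7335 in the same direction in both. Independent lists would share 698 genes above and 1382 below, against 2947 and 4388 observed. The differences correlated across genes with r = 0.920 (0.497 simulated), and their covariance was 0.366 against 0.0147 simulated, a difference of 0.351, part of which excess can come from the shared parental libraries. With same-numbered treated and untreated libraries as a replicate block and an estimated correlation, none of the lists passed for either difference. Of 31 p53 targets, 0 were above and 28 below the parental response in resistant 1 (adjusted p = 1.95e-13, or 0.0325 with an estimated correlation and 0.191 with a replicate block as well). In resistant 2, 0 were above and 27 below (0 and 28 adjusted over the list alone) (adjusted p = 7.38e-13, or 0.0351 with an estimated correlation and 0.124 with a replicate block as well). CDKN1A differed by -3.64 and -3.84 on the log2 scale (adjusted p = 4.6e-11 and 1.76e-11). Of 18 cancer-testis genes, 1 was above and 15 below in resistant 1 (adjusted p = 3.99e-10, or 0.0325 with an estimated correlation and 0.167 with a replicate block as well). In resistant 2, 1 was above and 15 below (adjusted p = 2.29e-08, or 0.0351 with an estimated correlation and 0.101 with a replicate block as well). Of 22 retinoic acid response genes, 2 were above and 16 below (3 and 16 adjusted over the list alone) in resistant 1, or 4 and 16 with a replicate block (adjusted p = 0.00263, or 0.0352 with an estimated correlation and 0.207 with a replicate block as well). In resistant 2, 1 was above and 17 below (1 and 18 adjusted over the list alone) (adjusted p = 0.000101, or 0.0229 with an estimated correlation and 0.101 with a replicate block as well). CRABP2 differed by -1.92 and -2.37 (highest adjusted p = 5.48e-09). The differences of DHRS3 (0.56, adjusted p = 0.045, and -0.56, adjusted p = 0.0422) no longer passed without any 1 of 9 libraries (0.0523 to 0.0996) in resistant 1 and without any 1 of 13 libraries (0.0509 to 0.202) in resistant 2.

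Of 21 cholesterol synthesis genes, which fell in parental cells, 16 were above and 0 below (17 and 1 adjusted over the list alone) the parental response in resistant 2 (adjusted p = 1.47e-06, or 0.0459 with an estimated correlation and 0.203 with a replicate block as well). In resistant 1, 11 were above and 1 below (12 and 1 adjusted over the list alone) (adjusted p = 0.000125, or 0.0956 with an estimated correlation). Of 6 squamous markers, 0 were above and 5 below in resistant 1 (adjusted p = 0.000135, or 0.0325 with an estimated correlation and 0.167 with a replicate block as well). In resistant 2, 0 were above and 6 below (adjusted p = 5.49e-05, or 0.0229 with an estimated correlation and 0.101 with a replicate block as well). Of 25 epithelial genes, 2 were above and 12 below in resistant 1 (adjusted p = 0.00176, or 0.0921 with an estimated correlation). In resistant 2, 1 was above and 15 below (adjusted p = 0.000155, or 0.0459 with an estimated correlation and 0.101 with a replicate block as well). Of 6 immune cell markers, 0 were above and 6 below in resistant 1 (adjusted p = 0.00112, or 0.0352 with an estimated correlation and 0.179 with a replicate block as well). In resistant 2, 0 were above and 5 below (0 and 6 adjusted over the list alone) (adjusted p = 0.00106, or 0.0379 with an estimated correlation and 0.106 with a replicate block as well). Selected for the strongest differences were SCD, HVCN1 (low in untreated resistant cells), the transcription factor AKNA and the complement receptor C5AR1 above the parental response, and CCNA1, TRIM43B, TAF11L14 and TRIM49C below it. SCD stood at 570.1 ± 34.6 CPM untreated and 587 ± 38.5 treated in resistant 1 (adjusted p = 0.76), and rose from 277 ± 20.6 to 386 ± 24.99 CPM in resistant 2. CCNA1 stood at 8.196 ± 0.519 and 11.96 ± 2.47 CPM in resistant 1 (adjusted p = 0.0786, passing without treated replicate 1 of resistant 1 or 2 (0.0464 to 0.0471)). In resistant 2 it rose from 0.732 ± 0.226 to 2.27 ± 0.749 CPM. Of the 1798 genes that rose by at least 2-fold in parental cells (median log2 response 1.49), 1123 rose in resistant 1 (median of all 1798, 0.43) and 727 in resistant 2 (0.23). Of the 702 that fell (median -1.22), 358 fell in resistant 1 (median -0.31) and 262 in resistant 2 (-0.24). These genes were chosen by their response in parental cells, which by itself favours a larger value there.

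**Figure D2:**
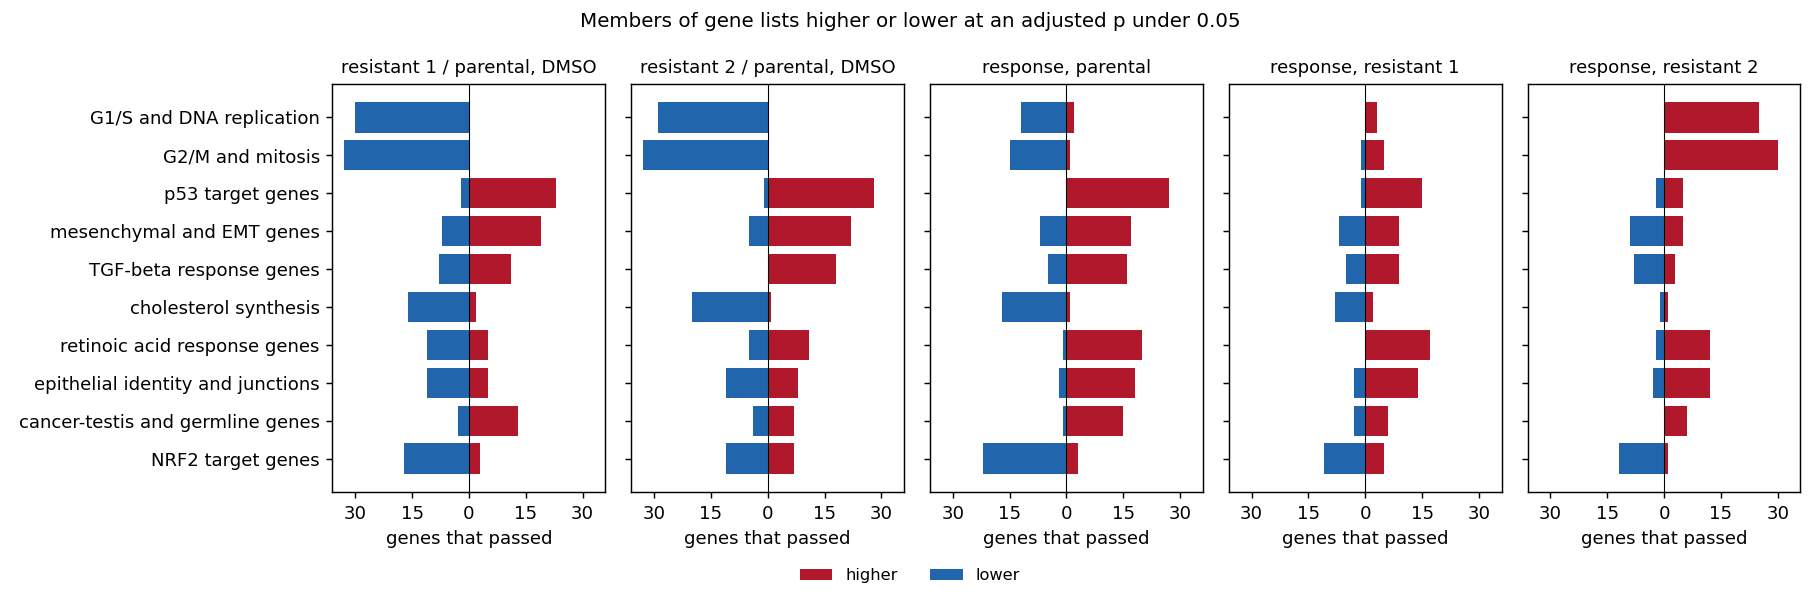
Numbers of members of 10 gene lists that were higher (right) or lower (left) at an adjusted p under 0.05 (limma), in the 2 resistant populations against parental cells with DMSO and in the treatment response of each population. All 33 G2/M genes were lower in both untreated resistant populations, and 30 of them rose with treatment in resistant 2.

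**Figure D3:**
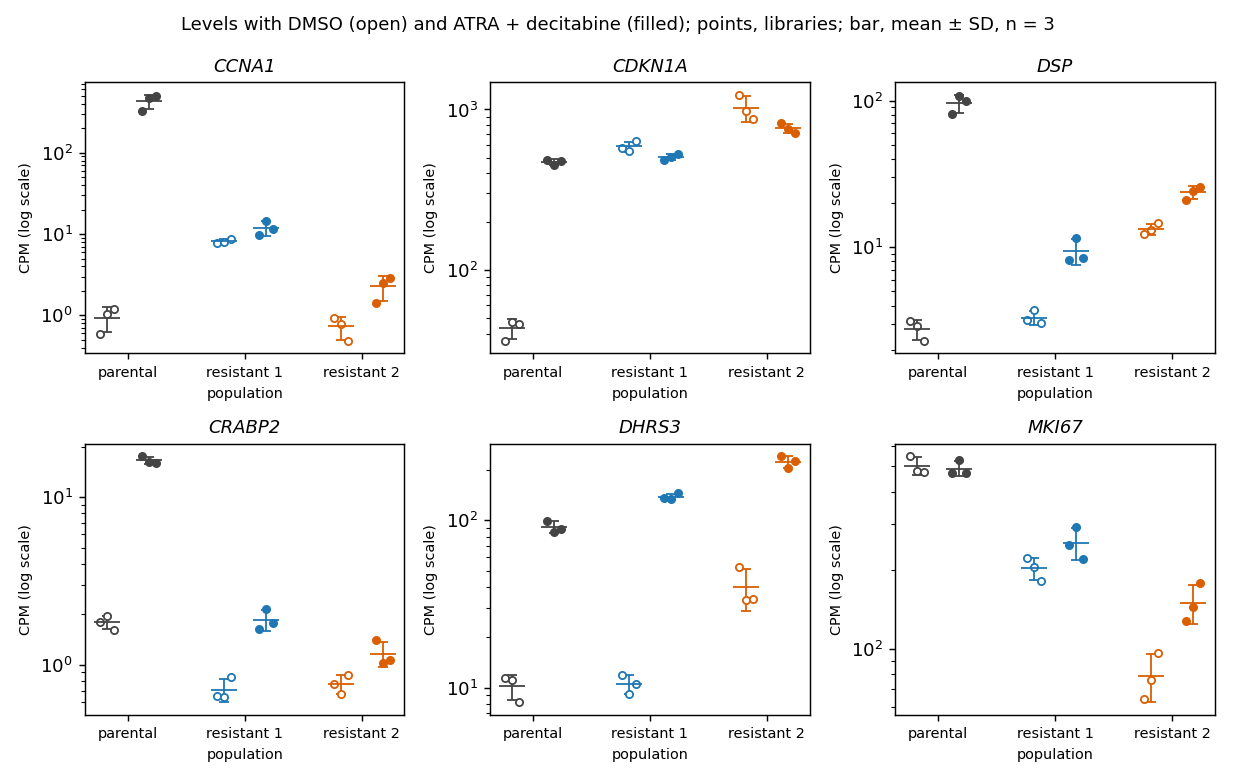
CPM (log axis) of 6 genes in each population with DMSO (open points) and with ATRA and decitabine (filled points). Points are libraries, and bars give the mean ± SD (n = 3). CCNA1 went from 0.941 to 429.7 CPM in parental cells, and DHRS3 from 10.5 to 139 CPM in resistant 1.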

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

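The treatment response differed between parental and resistant cells when the difference was tested. The splits of the libraries were planned, and the tests of the explanations were chosen after the result was seen. The response differed for 8448 genes in resistant 1 and 9551 in resistant 2 (limma, Benjamini-Hochberg). Of the genes named by rule, the log2 differences in resistant 1 and 2 were 3.32 and 2.98 for HVCN1, 2.59 and 2.99 for AKNA, 2.52 and 2.95 for SCD, and 2.57 and 2.45 for C5AR1. Below the parental response they were -7.38 and -7.60 for TRIM43B, -7.31 and -6.89 for CCNA1, -5.79 and -5.96 for TAF11L14, and -5.68 and -5.70 for TRIM49C. TRIM43B, TAF11L14 and TRIM49C have near-identical copies. HVCN1 was low in untreated resistant cells (8.29 and 42.3 normalized counts), so it could hardly fall.

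Of 100 splits of the libraries, the real one included, 1 gave as many genes as the 9551 of resistant 2 (highest other 8158). For the 8448 of resistant 1, 2 did (highest other 10002), a share under 0.05 for both. These splits shuffle populations and treatments together and ignore the same-numbered pairs. They test whether the groups differ at all, so they cannot decide whether the responses differ beyond chance. For the response within a population there are 10 splits, too few for a share under 0.05: the real values were 12735 in parental cells (highest other 0), 5729 in resistant 1 (highest other 1) and 3889 in resistant 2 (highest other 1054). Of the 10 splits, 4 part all 3 same-numbered pairs, and the highest other among these was 0 in resistant 1 and 0 in resistant 2, while the 6 that part 1 pair reached 1 and 1054.

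Choosing genes in parental cells is not the sole cause of the smaller rise. Genes chosen by their rise in resistant 1 rose by a median of 1.87 in parental cells and 0.82 in resistant 2, and those chosen in resistant 2 by 1.97 and 1.17 in parental and resistant 1 cells, so the smaller difference was 0.795. For genes that fell, those chosen in resistant 2 gave a difference of -0.176, so the choice of genes may explain part of the smaller fall. The check covers 354 and 216 risen and 73 and 88 fallen genes (at least 2-fold in resistant 1 or 2), not the 1798 or 702. Of the 702, 635 in resistant 1 and 643 in resistant 2 had a smaller response called. The 702 were chosen in parental cells. Of the genes that rose in parental cells, those not over 0.5 log2 higher in untreated resistant cells still rose less. They reached 34.7% of the parental median in resistant 1 and 18.9% in resistant 2, which speaks against genes being at their treated level from the start as the whole cause. Those over 0.5 log2 higher reached only 19.6% and 9.91%, so a part of the cause may lie there. A shift in scaling would lower risen and fallen genes alike, but genes chosen by their fall in resistant 1 or resistant 2 fell further in the other than in parental cells by only 0.0331 and 0.176 (95% bootstrap intervals -0.261 to 0.397 and -0.0781 to 0.439), at most 0.221 of the smaller rise, which argues against it as the whole cause. Lower uptake or activation of the drugs in the resistant cells remains untested.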

How the results depend on the processing

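The alternatives were written before the data were examined, except the posteriors of at least 0.9 and above, the log2(scaled count + 1) scale and the replicate block for the paired groups alone. With a threshold of 2-fold added, the counts with DMSO fell to 5988 in resistant 1, 7352 in resistant 2, 6255 for their mean, 5738 between them and 3505 in both. Under ATRA and decitabine they fell to 5283, 6440, 5254, 4386 and 3236. The response fell to 2500 genes in parental cells, 427 in resistant 1 and 304 in resistant 2, and the differences of responses to 1556 (390 above and 1166 below) in resistant 1 and 2035 (562 and 1473) in resistant 2. With the mean of the resistant populations tested on the compared groups alone, 7984 genes passed with DMSO and 9396 with ATRA and decitabine. With a replicate block for the paired groups, the response in resistant 2 (3889 to 5993) and the genes that fell in resistant 1 (2757 to 4156) and resistant 2 (1834 to 3085) grew by more than 1.5 times. Leaving out 1 library took the genes that fell down to 1650 or 1817 in resistant 1 and 1191 in resistant 2. Apart from these, and without the threshold of 2-fold, the totals of genes called and the numbers above and below within them stayed within 1.5 times. Quantile normalization shifted the median of all genes by -0.121, -0.108 and -0.112 for resistant 1, resistant 2 and their mean with DMSO.

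With the correlation estimated per list, the lists called with DMSO went from 16 to 0 in resistant 1, 13 to 2 in resistant 2, 16 to 0 for their mean and 12 to 0 between them. Under ATRA and decitabine they went from 13, 14, 16 and 7 to 0 each. For the response they went from 10 to 6 in parental cells, 10 to 2 in resistant 1 and 10 to 3 in resistant 2, and for the differences of responses from 12 to 5 in resistant 1 and 15 to 7 in resistant 2. With the replicate block for the paired groups as well, 1 list was left for the response in resistant 1, the retinoic acid response genes, and 0 for the response in resistant 2, for both differences and between the untreated resistant populations.

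Leaving out each library in turn gave, with DMSO, 10083 to 12474 genes in resistant 1, 11984 to 13209 in resistant 2, 11703 to 13224 for their mean, 9313 to 11788 between them and 6666 to 7806 in both. Under ATRA and decitabine the ranges were 11452 to 13700, 12544 to 14247, 12266 to 14215, 10023 to 11329 and 7672 to 9258. For the response they were 11283 to 13114 in parental cells, 3828 to 6027 in resistant 1 and 2864 to 3996 in resistant 2, and for the differences 7071 to 8960 and 8162 to 9751.

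Over all groups 22 of 45 same-numbered pairs of libraries correlated above 0.1 (from -0.798 to 0.938), and 17 of the 45 correlated best with their own number. A replicate block over all libraries called 11587, 12950, 12837, 10903 and 7396 genes with DMSO in the same order. It called 13306, 14329, 14205, 11570 and 9261 under ATRA and decitabine, and 13060, 6126, 4221, 8842 and 10024 for the responses and their differences. With the block for the paired groups alone, 12088 genes passed between the untreated resistant populations, 8030 for the response in resistant 1, 5993 in resistant 2, and 10596 and 11608 for the differences. The lists called with the preset correlation were 12, 11, 10, 13 and 16. Of 563 tests of named genes 46 gained the call and 2 lost it, and of the calls of single genes and of lists with the preset correlation printed in the text it changed only those given beside them.

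Over 1237 tests of named genes under the alternatives, 26571 of 27376 values kept direction and call, 509 lost the call, 292 gained it and 4 reversed. Quantile normalization reversed CDKN1A (-0.1807) and SCD (-0.03182) in resistant 1 against parental cells under ATRA and decitabine. The difference of responses of MTATP6P1 in resistant 2 became -1.70 with edgeR and -0.02321 on the scaled count scale, since it has 1 read there without and 0 with treatment. The cause of the other changes was not tested.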

Other observations

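All tests of explanations in this part other than the splits of the libraries were chosen after the results were seen. In untreated resistant cells, further gene groups differed. Of 18 antigen presentation genes, 12 were higher and 1 lower in resistant 1 (adjusted p = 0.00273, or 0.35 with an estimated correlation). In resistant 2, 11 were higher and 1 lower (11 and 3 adjusted over the list alone) (adjusted p = 0.0314, or 0.495 with an estimated correlation). HLA-B, a class I gene with close relatives and so uncertain, stood at 1975 ± 55.6, 13596 ± 422 and 17078 ± 3437 normalized counts in parental, resistant 1 and resistant 2 cells. Of 22 targets of YAP and TAZ, 12 were higher and 3 lower in resistant 1 (adjusted p = 0.016, or 0.365 with an estimated correlation). In resistant 2, 14 were higher and 5 lower (15 and 5 adjusted over the list alone) (adjusted p = 0.00685, or 0.406 with an estimated correlation). The receptor kinase AXL stood at 1453 ± 44.9, 16509 ± 967 and 10645 ± 2351. Of 13 neuroendocrine markers, 8 were higher and 2 lower in resistant 1 (adjusted p = 0.0141, or 0.259 with an estimated correlation). In resistant 2, 9 were higher and 1 lower (adjusted p = 0.0101, or 0.291 with an estimated correlation). Chromogranin B (CHGB) stood at 33.97 ± 13.5, 142 ± 9.49 and 611 ± 98.4. The 43 type I interferon response genes did not pass as a list (adjusted p = 0.387 and 0.0972), although XAF1, a pro-apoptotic interferon target, stood at 1.73 ± 1.31, 65.1 ± 8.53 and 389 ± 107. Under ATRA and decitabine, 20 of 27 glycolysis and hypoxia genes were higher and 2 lower in resistant 2 (adjusted p = 0.00335, or 0.402 with an estimated correlation), with VEGFA at 8266 ± 455 in parental cells and 58541 ± 6984 in resistant 2.

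Genes that rose with treatment in parental cells were mostly higher in untreated resistant cells: 70.4% of the 1798 were higher in resistant 1 and 68.1% in resistant 2, and of the 702 that fell, 24.8% and 30.9% were higher. Over all genes 50.3% and 49.2% were higher. The untreated parental libraries enter both sides, which alone favours such shares. Across 18537 genes the parental response and the untreated difference correlated with r = 0.322 and 0.318 (0.505 and 0.502 in simulated unchanged groups). The signs agreed for 61.5% and 60.7% of genes (67.05% and 66.96% simulated). Shared noise of any size gives such values, so they cannot decide. The covariance was 0.186 against 0.00749 simulated (a difference of 0.179) and 0.219 against 0.00744 (0.212). This argues against shared noise as the whole cause across genes. A total of 2668 genes rose and were higher in resistant 1 and 2539 fell and were lower, against 1689 and 1647 for independent lists. In resistant 2 the counts were 2836 and 2786 against 1908 and 1814.

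Targets of DUX4, a transcription factor of the cleavage-stage embryo, rose in treated parental cells. Of 42 listed targets 9 were named before the list was written. Of the other 33, 10 were tested, 9 rose in parental cells, and all 10 responded less in both resistant populations (median log2 response 0.0182 and 0, against 2.84). For 6, tested only for their treated parental reads, the filter fixed both results. Treated parental levels were 28.5 CPM for LEUTX, 26.8 for TPRX1 and 39.2 for RFPL4A. DUX4 itself had 48 reads over the treated parental libraries and 0 over the untreated ones. Reads shared between near-identical copies do not account for all of this rise. Of the 4 tested targets listed as without such a copy and not named before, 3 rose by at least 2-fold, just the number set as enough. Of 981 other silent genes 740 were called as risen. The median of the 981 was 0.24, against 2.86 for the 6 silent targets of the 10. In a permutation test, no random silent set of 10000 reached 2.86 (highest 1.75, p = 1e-04, its minimum). Random sets treat genes as independent, which PRAMEF5 and PRAMEF6 of 1 family are not, so p may be too small. The 981, unlike the 6, could pass the filter by resistant reads, so this cannot tell if a general rise gives the size. DUX4 activity is a candidate explanation, found and tested on the same data.

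Nuclear copies of mitochondrial genes had many reads in parental libraries and almost none in resistant ones. Of 399 such copies 20 had at least 20 reads in each parental DMSO library, and 19 of these, on 6 chromosomes, had 6 reads in all over the 6 resistant libraries, the exception being MTCO2P2. Of 17 neighbours within 200 kb that reached the same level, 0 were lost, which argues against loss of wide chromosome regions. Their median log2 fold changes were -0.341 in resistant 1 and -0.028 in resistant 2, and the lowest -2.325 and -0.844. Losses that spare the neighbours, or copies without such a neighbour, are not covered. Copies that share exact 50-base windows with mitochondrial transcripts reached it far more often (14 of 16 against 6 of 383, a ratio of 55.9, or 15 and 13 with at least 1 read in each), so mitochondrial reads counted on the copies may be their source. Whether mitochondrial reads were removed more completely from the resistant libraries or the resistant cells held fewer mitochondrial transcripts cannot be told apart, because the mitochondrial genes themselves had 0 reads in all 18 libraries. No label gives separate handling of the populations.

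For the comparisons of populations, each of 3 libraries against 3, there are 10 splits, too few for a share under 0.05. With DMSO the real values were 12102 in resistant 1, 13402 in resistant 2 and 11555 between them, and under ATRA and decitabine 13191, 14216 and 11475, and the highest other value was 0 in each. For the mean of both resistant populations, 1 of 100 splits, the real one, gave as many genes (13300 with DMSO, highest other 13011, and 14109 with ATRA and decitabine, highest other 13316). The same holds for genes called in both (7782, highest other 7243, and 9174, highest other 7322), a share under 0.05 for these 4 counts. The splits mix 3 populations, so this share speaks only against the absence of any difference between them. It does not measure how far the resistant populations as such differ from parental cells. The high values of other splits point to the large differences between the 3 populations, which any uneven mixing keeps.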
